A study of Rattus norvegicus with 24 samples.

How the data were processed

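The values are log2 signals as deposited, for 31099 probe sets on 24 rat arrays. The program that summarised the probes is not given in the sources used here. Per the labels' protocols, germ cells were freed with collagenase and trypsin and enriched by sedimentation in a density gradient, RNA was taken with a Qiagen kit, and biotinylated cRNA was made from total RNA. Replicates are separate rats per the labels, and the labels hold no batch information. Both fractions of a rat were joined by the number in the labels. After removing group means, the own fractions of a rat correlated at -0.07 to 0.36, and a rat's own partner was the best match for 6 of 12 rats, so the pairing was weakly visible in the values.

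The pachytene and round spermatid arrays differ in how low signals were treated. The mean of an absent control was 4.28 in pachytene arrays and 6.83 in round spermatid arrays. Cell type and the background of the arrays therefore cannot be told apart for dim probe sets. For comparisons across cell types, an offset of 90.6, which was not in the plan, was added to the linear pachytene values. It was chosen so that 45 control probe sets matched (mean difference 0.61 ± 0.77 before, -0.03 ± 0.17 after; SD over control probe sets), and the 24 arrays were then quantile normalized. A difference between cell types still holds any effect of processing that the controls do not carry, and folds of dim transcripts are compressed.

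Array medians spanned 0.763 in pachytene spermatocytes (6.62 to 7.38) and 0.307 in round spermatids (7.56 to 7.86). The plan called for quantile normalization if the values were not already normalized, and these spans led to it, within each cell type for the age comparisons. Hybridization control levels were 11.5, 11.4, 11.6 and 11.6 in young and aged pachytene spermatocytes and young and aged round spermatids. With 6 rats per age, small changes in the whole distribution cannot be separated from changes in RNA content.

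The comparisons, tests, gene lists, thresholds and the rule for naming genes were written before the data were examined. Exceptions were the background offset, the relations between list levels and the test of all somatic cells alike. Moderated t tests (limma, lmFit and eBayes with default settings) were run on 31042 probe sets, after leaving out 57 control probe sets. The Benjamini-Hochberg adjusted p threshold was 0.05. Age was tested within each cell type, the cell types and the difference of the age effect over 4 group means on all arrays. A gene was represented by its brightest probe set among the 20826 with exactly 1 symbol. Named genes are the 10 largest changes in each direction past the threshold (5 for the difference), and up to 4 members of a list with the smallest p; symbols starting with LOC, RGD or MGC were counted and not named. Of 14217 gene identifiers, 14167 were found in the reference, which placed genes on chromosomes of assembly GRCr8. Rgs7bp, Plekha6 and C1s are named as exceptions to this rule, from a screen written after the values were seen.

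In total 32 gene lists from textbook knowledge were tested with camera (preset correlation 0.01), adjusted over lists within each comparison, on lists with at least 5 measured members. Agreement between cell types was measured by correlation of log2 changes across probe sets. Relations between list levels were tested by exact permutation within age. Groups of rats were drawn anew 100 times to compare the counts with those of other splits.

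The alternatives written down beforehand were median centring, leaving out the 40% dimmest probe sets, eBayes with trend and robust, array weights, a fold threshold of 1.5 with adjusted or unadjusted p, leaving out probe sets that can cross-hybridise, 1 probe set per gene, leaving out each rat, the rat as random or fixed block, a block over shared numbers, marker levels as covariates, each age alone, an estimated correlation between genes, fry, and the mean over a gene's probe sets. Chosen after the values were seen were the deposited scale, centring on hybridization controls, cyclic loess, both marker covariates together, late spermiogenesis with somatic covariates, and leaving out young rats 1, 10 and 11 or young rat 10. The background offset was not in the plan either. The fit without it, as planned, gave 26467 calls between cell types and 3614 for the difference.

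The fits were also tried on made changes, with 50 probe sets changed at each fold. Changes of 1.5-fold were recovered in 80% of cases in pachytene spermatocytes, 98% in round spermatids, 100% between cell types and 92% for the difference. Changes of 1.25-fold were recovered in 36%, 86%, 86% and 60%. Of the unchanged probe sets 10, 14, 19 and 7 were called, and of 20 random lists 1 was called in pachytene spermatocytes and 0 elsewhere. The noise of the made arrays was drawn independently for each probe set, while genes of the real arrays vary together. These rates therefore do not carry over to the real arrays, least of all for lists. R 4.3.3, limma 3.58.1, the data.table package (1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used.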

Results

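RNA was measured on 24 Affymetrix rat arrays in germ cell fractions of Brown Norway rats that were 4 months old (young) or 18 months old (aged). Pachytene spermatocytes are in the long prophase of meiosis, and round spermatids are the haploid cells that follow it. Each of the 4 groups held 6 arrays, and by the numbers in the labels each of 12 rats gave both fractions, so the number of rats limits the precision. Of 31042 probe sets tested, 20826 carried 1 gene symbol, for 14217 genes. The median log2 level of an array was 7.17 ± 0.15 (SD, n = 6) in young pachytene spermatocytes, 6.79 ± 0.12 in aged ones, 7.64 ± 0.05 in young round spermatids and 7.77 ± 0.07 in aged ones. Arrays of a group correlated at 0.971 to 0.998 in young pachytene spermatocytes, at 0.996 to 0.998 in aged ones, at 0.978 to 0.997 in young round spermatids and at 0.996 to 0.999 in aged ones. On the deposited scale the median probe set was shifted by -0.24 in aged pachytene spermatocytes and by 0.14 in aged round spermatids, and when arrays were centred on hybridization controls by -0.12 and 0.18. All age changes are therefore given relative to the whole distribution of an array, after quantile normalization, unless another scaling is named. With median centring of each array, that shift was 0.13 in pachytene spermatocytes.

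The first comparison asked which transcripts separate the fractions. Among single genes, Fscn3 and Ace were among the 10 largest differences towards round spermatids. Fscn3 (1383657_at), an actin-bundling gene of the testis, was 8.07-fold higher in them (log2 difference 3.01, SE 0.25, n = 12 arrays per cell type, adjusted p = 8.00e-11). Ace (1387791_at), whose testis form is made in spermatids, was 6.98-fold higher (2.80, SE 0.18). Tex46, Ica1, Slc6a6, Hipk4, Adam4, Ccsap, Fbxo39 and C13h1orf21 were the other genes with the largest differences in that direction. Pachytene spermatocytes held more Gmcl1 (1375960_at; 19.1-fold, log2 difference -4.26, SE 0.10), Sprtn (17.1-fold), Pbk (15.1-fold) and Ccne2 (13.2-fold), a cyclin of the cell cycle. B3galnt1, Tgfa, Phf2, Hace1, Myef2 and Tbl2 completed the 10 largest differences towards pachytene spermatocytes. For Gmcl1, Ccne2 and Tbl2, 1 other probe set each was past the threshold in the opposite direction. In round spermatids Tgfa (1381449_s_at) lay at 6.69 ± 0.06 and 6.73 ± 0.01 in young and aged rats (n = 6 each), so its difference (14.6-fold, adjusted p = 1.06e-21) was measured against the background of those arrays.

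Marker lists followed the same split. Of 24 late spermiogenesis markers 21 were higher in round spermatids and 0 lower, and of 17 round spermatid and acrosome markers 15 were higher and 1 lower, among them Acr (3.07-fold), the protease of the acrosome, and Acrbp (2.10-fold). The median of the acrosome list lay 0.92 above that of all genes (camera, adjusted p = 0.00373), and that of the late list was higher still (adjusted p = 0.000633). With an estimated correlation neither call held (adjusted p = 0.435 and 0.534). Of 13 genes of the piRNA pathway 10 were lower in round spermatids and 3 higher (median -1.04, adjusted p = 0.00719; 0.435 with an estimated correlation), with Prmt5 5.11-fold and Piwil2 5.09-fold lower. Of 16 pachytene markers 11 were lower and 4 higher, with Tdrd1 7.45-fold and Mybl1 8.34-fold lower, and the list was not past the threshold (adjusted p = 0.0816). Of these markers 3 are on the piRNA list too. Sycp2 (3.96-fold) and Sycp3 (2.52-fold), which build the synaptonemal complex, were lower, while Syce3 was 3.15-fold higher. That list of 13 had 6 genes higher and 7 lower (adjusted p = 0.509). The cilium and flagellum list was split too, with 51 of 100 higher and 44 lower (adjusted p = 0.945).

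Genes of protein synthesis and respiration were lower in round spermatids. Of 44 cytosolic ribosomal protein genes 42 were lower and 2 higher (median -0.72 relative to all genes, adjusted p = 5.10e-12; 0.435 with an estimated correlation), as Rpl6 (2.96-fold), Rpl7a and Rpl23. Of 79 respiratory chain and ATP synthase genes 61 were lower and 13 higher (median -0.62, adjusted p = 2.08e-07; 0.435 with an estimated correlation), with Atp5mc3 4.82-fold lower and Cox7a1 higher by 0.56. Lower too were 51 of 73 mitochondrial ribosomal protein genes (9 higher; median -0.39, adjusted p = 8.92e-05), 29 of 36 proteasome genes (7 higher; median -0.47, adjusted p = 0.000201; Psmd6, 4.67-fold) and 23 of 32 nucleotide excision repair genes (5 higher; median -0.53, adjusted p = 0.000804). With an estimated correlation these calls were lost as well (adjusted p = 0.503, 0.435 and 0.435). Of 51 chaperone genes 29 were lower and 14 higher (median -0.32, adjusted p = 0.0426). That call was lost with an estimated correlation (adjusted p = 0.435), with median centring (0.169), on the deposited scale after the background offset (0.228), without the 40% dimmest probe sets (0.0691), without young rat 1 (0.0587) or young rats 1, 10 and 11 (0.0631), and in aged rats only (0.0927).

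Sertoli cell markers were high in the pachytene fraction and lower in round spermatids (20 of 25 lower, 4 higher; median -1.22, adjusted p = 8.92e-05; 0.503 with an estimated correlation). Clu (8.65-fold), Aard (8.59-fold), Cst12 (8.47-fold) and Cldn11 (7.76-fold) led that list. Macrophage markers (28 of 34 higher, 4 lower; median 0.40, adjusted p = 0.00889; 0.534 with an estimated correlation) and peritubular markers (11 of 13 higher, 1 lower; median 0.30, adjusted p = 0.0475; 0.563) went the other way. Both lists were dim in young pachytene fractions, with 6 of 34 macrophage and 4 of 13 peritubular markers above the median of all genes. Their differences therefore cannot be told apart from the background of the arrays and the offset. The peritubular call was lost with median centring (adjusted p = 0.0888), on the deposited scale after the background offset (0.0629), without the 40% dimmest probe sets (0.0742), in young rats only (0.0732), without young rats 1, 10 and 11 (0.0585) and without any 1 of young rats 3, 10 and 13 or aged rats 2, 3 and 5 (0.0509 to 0.0568). The X chromosome as a whole did not separate the fractions (231 of 445 genes higher, 152 lower, camera adjusted p = 0.42). Most X genes were dim in both, with 112 of 445 above the median of all genes in young pachytene fractions and 125 in young round spermatids. The background of the arrays and the offset could therefore hide a difference. In all, 26420 of 31042 probe sets differed (85.1%), 14549 higher and 11871 lower in round spermatids, and 4489 of them at least 2-fold. With the list's correlation estimated from the arrays none of the 12 list calls held (adjusted p = 0.435 to 0.563). Adjusted over the list alone, the counts of the lists given here matched those over all probe sets except for 1 more gene higher among acrosome markers (16), respiratory genes (14) and X genes (232).

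Age was compared next within pachytene spermatocytes. The means of X-linked genes and of Sertoli cell markers were lower in every aged rat than in any young one. Smarca1 (1384437_at), an X-linked chromatin remodeller, fell from 7.43 ± 0.26 to 5.95 ± 0.31 (SD, n = 6; 2.80-fold, SE of the log2 change 0.15, adjusted p = 0.000231). Rbm3, an X-linked RNA-binding protein gene, fell 2.76-fold, Pja1 2.61-fold and Armcx2 2.33-fold. Of 445 X chromosome genes 241 fell and 14 rose, and the list's median relative to all genes was -0.45 (camera, adjusted p = 1.35e-17; adjusted p = 0.75 with an estimated correlation). Adjusted over the list alone, 256 fell and 19 rose. The share of genes that fell was 54.2% on the X chromosome and 14.4% to 23.8% on the 20 autosomes (places from assembly GRCr8). The mean of the X genes relative to all genes was -1.27 ± 0.20 in young and -1.70 ± 0.06 in aged rats, and all 6 aged arrays lay below every young one.

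**Figure D1:**
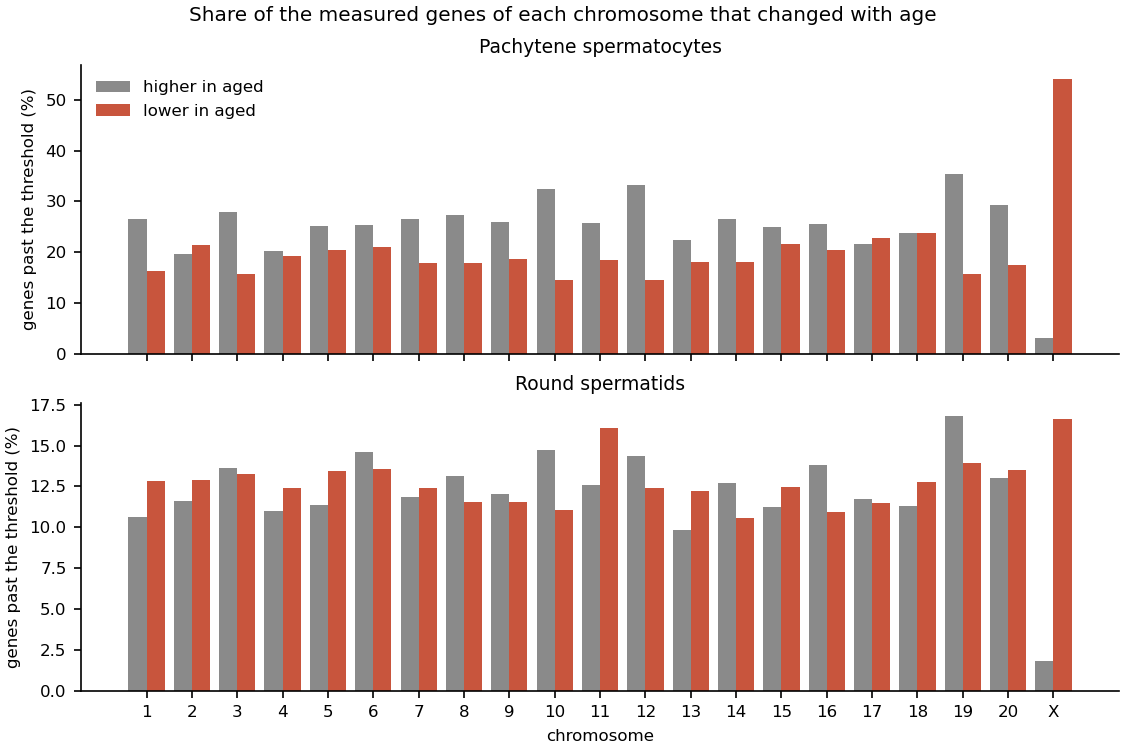
Share of the measured genes of each chromosome (percent) that were higher (grey) or lower (red) in aged rats at an adjusted p threshold of 0.05, in pachytene spermatocytes (top) and round spermatids (bottom). On the X chromosome 54.2% of 445 genes were lower in aged pachytene spermatocytes and 16.6% in aged round spermatids. Most X genes were dim on the round spermatid arrays, where falls are compressed. The shares are from quantile-normalized values, and on the deposited scale 394 of the 445 were lower in pachytene spermatocytes, where 17801 of 31042 probe sets were lower.

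X genes were also split by their level in round spermatids, without a test of the split. Among 159 X genes with a lower level in round spermatids than in pachytene spermatocytes, 120 fell with age in pachytene spermatocytes and 2 rose (median -0.84 relative to all genes). Among 223 with a higher level in round spermatids, 102 fell and 7 rose (median -0.28). Among other genes, 1299 of 5548 fell and 1599 rose when lower in round spermatids (median 0.02), and 1034 of 6613 fell and 1546 rose when higher (median -0.01). Young rats 1, 10 and 11 stood apart on the first principal component (73.9% of the variance; -86.3, -47.1 and -44.0, against -7.38 to 3.78 in the other young rats). Without them the X median was -0.23, with 184 genes lower and 10 higher.

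Sertoli cell markers fell in aged pachytene fractions. Of 25 measured, 20 fell and 0 rose (21 and 0 adjusted over the list alone), and their median relative to all genes was -1.02 (camera, adjusted p = 3.61e-10; 0.75 with an estimated correlation). Inha (1387124_at), a subunit of inhibin, fell from 10.1 ± 0.26 to 8.87 ± 0.29 (2.40-fold, adjusted p = 0.000273). Cst12 fell 2.39-fold, the transcription factor Wt1 2.31-fold and Aard 2.27-fold. All 6 aged arrays lay below every young one in the list's mean (1.51 ± 0.28 and 0.80 ± 0.12 relative to all genes). The same separation held for lists not past the threshold, with spermatogonia, antioxidant, apoptosis, ubiquitin and glycolysis genes lower and pachytene marker, DNA break repair and cell cycle genes higher in all 6 aged arrays. Other somatic lists were not past the threshold, and most of their genes lay below the median of all genes in young fractions, where a fall is hard to see. Of 19 Leydig cell markers 1 rose and 6 fell (adjusted p = 0.186), of 13 peritubular markers 5 rose and 2 fell (0.416), of 34 macrophage markers 7 rose and 2 fell (0.661), and of 15 endothelial and blood markers 3 rose and 1 fell (0.207). Of 20 spermatogonia markers 3 rose and 5 fell (0.186), the latter including Etv5 (-1.15, SE 0.16), Pou3f1 (-1.09), Ccnd2 (-0.65) and Dmrt1 (-0.57).

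Late spermiogenesis markers fell as well. Of 24, 17 fell and 3 rose, before and after being adjusted over the list alone (median -0.75; camera, adjusted p = 0.000461; 0.832 with an estimated correlation). Hils1, a spermatid linker histone, fell 1.89-fold, Smcp, of the sperm mitochondrial capsule, 1.71-fold, and Odf1, of the outer dense fibres, 1.59-fold. Ggn rose by 0.44 (SE 0.07), and its change was 0.02 (adjusted p = 0.836) on the deposited scale and 0.14 (0.255) with hybridization controls. The list's call was lost on the deposited scale (adjusted p = 0.576) and with hybridization controls (0.243). Without young rats 1, 10 and 11 the median was -0.36, with 11 genes lower and 1 higher, and with median centring 11 were lower and 7 higher. Odf1 (adjusted p = 0.0588) lost its call with median centring. Young rats 1, 10 and 11 held the highest levels of the list, which lay at 4.50 ± 0.39 in young and 3.93 ± 0.15 in aged rats, 5 of 6 aged arrays below every young one.

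**Figure D2:**
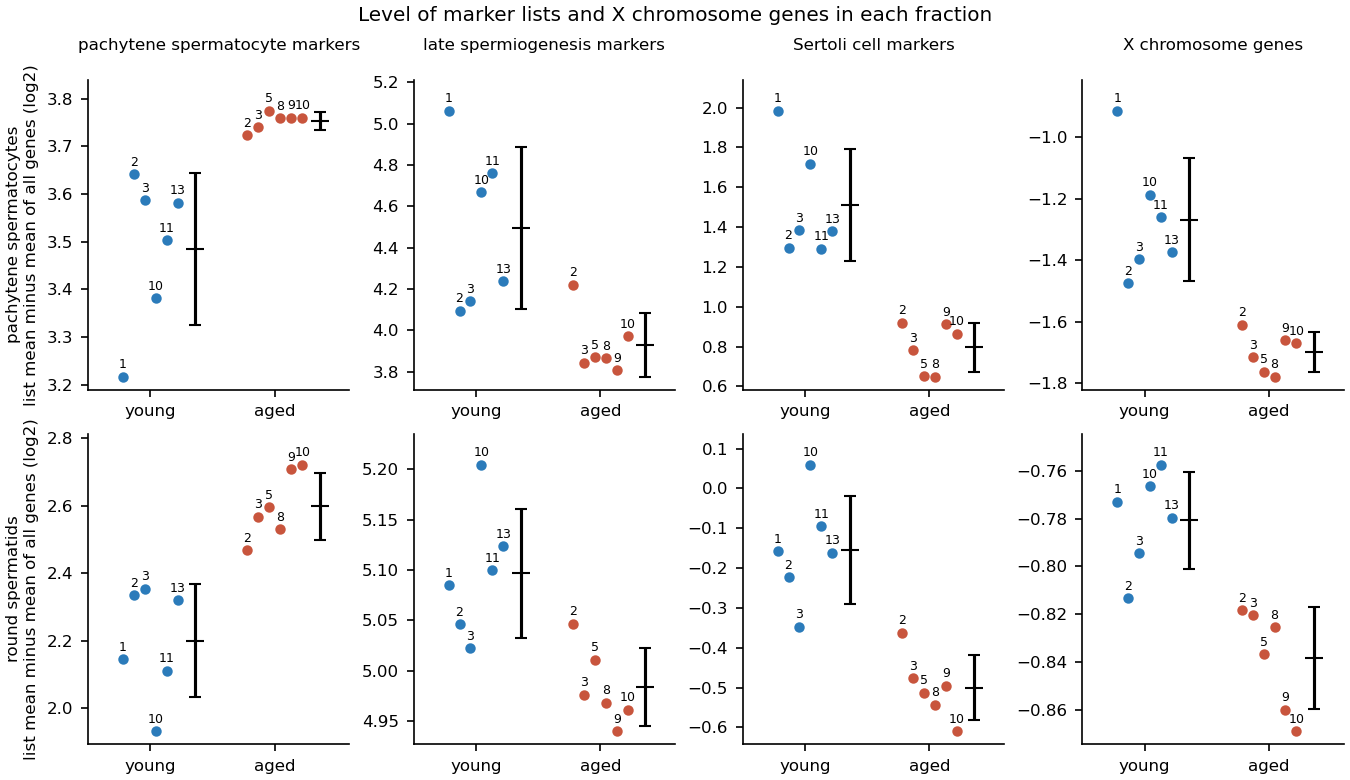
Mean log2 level of 4 gene lists minus the mean of all genes, per array, in pachytene spermatocytes (top) and round spermatids (bottom); points are rats by number, bars the mean and SD of 6 arrays. Sertoli cell markers and X chromosome genes were lower in all 6 aged arrays than in every young array of the same cell type, and pachytene spermatocyte markers were higher. The medians of the Sertoli and X lists relative to all genes keep their sign with cyclic loess and without the quantile step. Scalings that only shift whole arrays cannot move these medians.

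Single genes of cell division rose in aged pachytene spermatocytes, while their lists were not past the threshold. Cdk1 rose 1.75-fold (log2 change 0.81, SE 0.17, adjusted p = 0.00427), Aurka 1.71-fold, Plk1 by 0.58 and Pttg1 1.45-fold; the first 3 encode kinases that drive cell division. Of 48 genes of cell cycle and meiotic division 19 rose and 7 fell (22 and 8 adjusted over the list alone; camera, adjusted p = 0.186), and of 16 pachytene markers 5 rose and 1 fell (6 and 1; 0.186). These lists share 7 genes, Cdk1, Aurka, Plk1 and Pttg1 included, so their counts overlap. Of 46 genes of DNA break repair and damage signalling 18 rose and 1 fell (19 and 1; 0.22), among them Slx4 (0.60), Fancd2 (0.60), Bard1 (0.66) and Fanca (0.41). On the deposited scale Fanca had a change of -0.02 (adjusted p = 0.788) and Bard1 lost its call (0.0819), and with hybridization controls Fanca did (0.383). Of 51 antioxidant genes 11 rose and 20 fell (14 and 20 adjusted over the list alone; 0.0519), with Prdx2 2.28-fold, Mgst1 2.15-fold, Gstm2 2.12-fold and Gstp1 1.95-fold lower. Of 25 glycolysis genes 4 rose and 11 fell (5 and 11; 0.189), with Ldhb 2.32-fold, the lactate transporter Slc16a1 2.19-fold, the X-linked Pgk1 2.06-fold and Pgam1 1.78-fold lower.

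Further lists were not past the threshold in pachytene spermatocytes. Mitochondrial ribosomal protein genes had 26 of 73 that rose and 10 that fell (33 and 10 adjusted over the list alone; adjusted p = 0.0519), and ubiquitin genes 20 of 124 that rose and 41 that fell (0.0519). Chaperones had 13 of 51 each way (0.939), and their median (0.06) and mean (-0.06) differed in sign; Hspd1 fell 1.99-fold, Hspa4 1.74-fold, Bag2 1.67-fold and Hsp90ab1 1.41-fold, the last not past the threshold with median centring (0.0550). Base excision repair had 8 of 30 that rose and 9 that fell (0.652; Hmgb1 fell 2.27-fold), nucleotide excision repair 14 of 32 and 6 (0.661), and mismatch repair 5 of 17 and 4 (0.95). The cilium and flagellum list had 34 of 100 that rose and 14 that fell (0.25), acrosome markers 3 of 17 and 7 (0.22), the synaptonemal complex list 2 of 13 and 4 (0.25), and piRNA genes 2 of 13 and 2 (0.841). Apoptosis regulators had 6 of 33 that rose and 8 that fell (0.416), the proteasome 7 of 36 each way (0.95), the respiratory chain 8 of 79 and 13 (0.832), and cytosolic ribosomal proteins 2 of 44 and 4 (0.416). Inflammatory genes had 9 of 37 that rose and 2 that fell (0.345), the unfolded protein response 9 of 32 each way (0.95), chromatin modifiers 14 of 62 and 15 (0.538), cholesterol synthesis 9 of 22 and 7 (0.972), and extracellular matrix 12 of 39 and 8 (0.95). Adjusted over the list alone, the counts were 13 that rose and 9 that fell for the unfolded protein response, 36 and 16 for the cilium list, 13 and 9 for extracellular matrix, 9 and 9 for base excision repair, 15 and 6 for nucleotide excision repair, 6 and 9 for apoptosis regulators, 9 and 7 for the proteasome, 5 and 13 for the respiratory chain, 1 and 0 for cytosolic ribosomal proteins, 14 and 16 for chromatin modifiers, 1 and 2 for piRNA genes, 8 and 2 for inflammatory genes, 7 and 2 for peritubular and 2 and 6 for Leydig cell markers, and unchanged for the others of this paragraph. Median and mean change also differed in sign for extracellular matrix, base excision repair, apoptosis regulators, the proteasome, the respiratory chain, cytosolic ribosomal proteins and the unfolded protein response.

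The largest rises in pachytene spermatocytes came with a wide spread among young rats. Skor1 (1377289_at), a transcriptional corepressor, rose from 7.20 ± 1.65 to 9.51 ± 0.21 (4.97-fold, SE of the log2 change 0.59, n = 6, adjusted p = 0.0101). Gem (1382351_at), a small GTP-binding protein gene, rose from 6.65 ± 1.48 to 8.62 ± 0.29 (3.92-fold, adjusted p = 0.0135). Klkb1, Ets2, Igtp, Ddit4l, Bhlhe41, Slco3a1, Sptbn4 and Cacna1h rose by 1.80 to 1.54 on the log2 scale. Without young rats 1, 10 and 11 the rise of Skor1 was 0.84 and that of Gem 0.63, and the 10 genes ranged from 0.33 (Cacna1h) to 0.95 (Klkb1), each past the threshold. Cacna1h lost its call without young rat 10 or 11 or aged rat 5, 8 or 9 (adjusted p = 0.0501 to 0.0613), and with array weights Cacna1h (0.0894) and Ddit4l (0.0543) did.

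Among the 10 largest falls, some were even and some were not. Gca (1390557_at), a calcium-binding protein gene, fell from 9.34 ± 0.24 to 7.71 ± 0.45 (3.10-fold, adjusted p = 0.000273), and Cttnbp2, Zbtb41 and Shc4 fell 2.94-, 2.86- and 2.80-fold. Without young rats 1, 10 and 11 the changes of Gca (-1.60), Cttnbp2 (-1.40), Zbtb41 (-1.51) and Shc4 (-1.30) moved little. The monocarboxylate transporter gene Slc16a7 (1370609_a_at) fell from 12.4 ± 0.90 to 10.9 ± 0.30 (2.95-fold, adjusted p = 0.00447), and its change was -0.83 without those rats. The changes of Prl7d1 (-1.51), Zfp455l1 (-1.49) and Tubb2a (-1.47) became -0.74, -0.77 and -0.94. Cxadr (1384816_at), a cell adhesion gene of tight junctions, fell from 6.18 ± 1.49 to 4.67 ± 0.06 (adjusted p = 0.0396), and the fall rested on 4 young rats. Young rats 1, 2, 3 and 11 had levels of 6.17 to 8.18, while the other 2 young rats (4.36 to 4.68) lay with the aged ones (4.60 to 4.77). Leaving out any 1 rat other than young 10 and 13 ended the call of Cxadr (adjusted p = 0.052 to 0.0831).

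**Figure D3:**
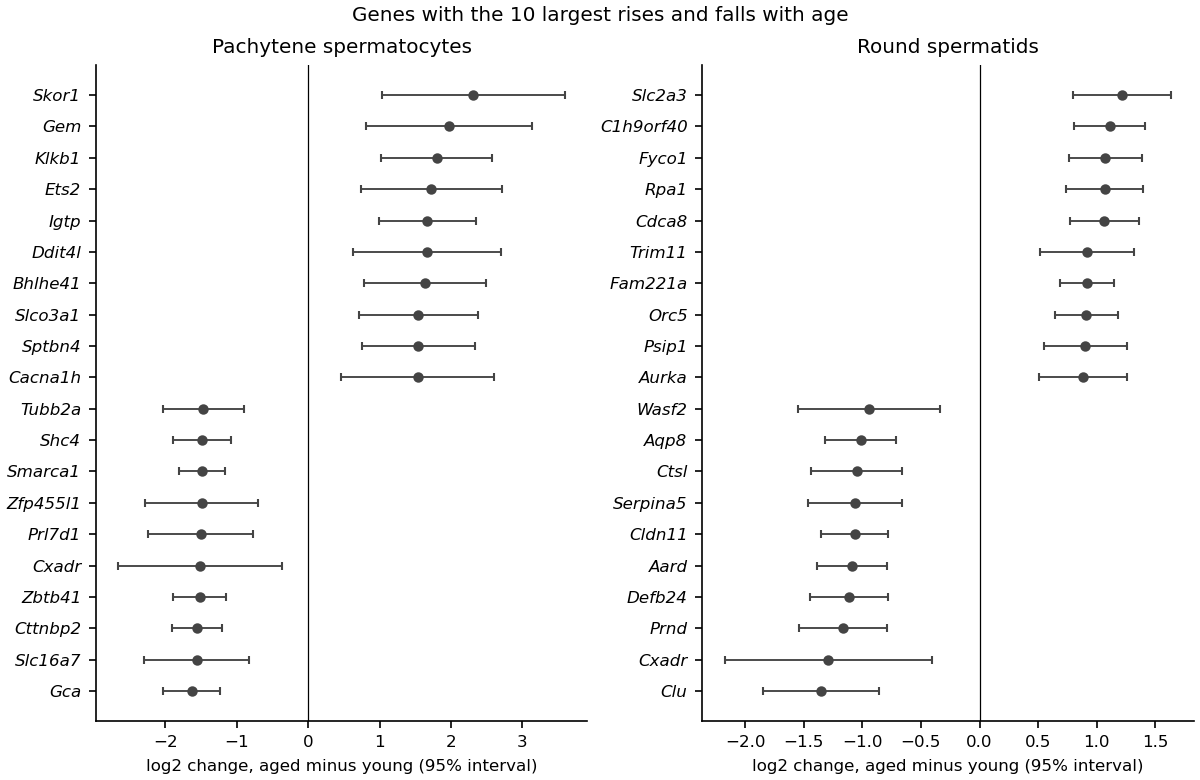
Log2 change (aged minus young) of the genes with the 10 largest rises and 10 largest falls in pachytene spermatocytes (left) and round spermatids (right), with 95% intervals over 6 rats per age. The intervals of Skor1 (2.31) and Gem (1.97) are wide, and that of Smarca1 (-1.49) is narrow; the changes shown keep their sign under every scaling tried.

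Over all probe sets, 11643 of 31042 (37.5%) were past the threshold in pachytene spermatocytes (limma), 6866 higher and 4777 lower in aged rats. At a fold of at least 2 there were 131 higher and 723 lower. The direction of the many small changes followed the scaling, with 10625 higher and 4161 lower after median centring, 4665 and 5905 with cyclic loess, 2256 and 7903 with hybridization controls, and 1352 and 17801 on the deposited scale. Using late spermiogenesis and somatic marker levels as covariates left 136 higher and 965 lower, a fit whose late spermiogenesis covariate nearly separates the ages. In that fit 25 of the 56 genes named here lost their call, 3 more changed sign (Gem, -0.06; Ddit4l, -0.07; Cacna1h, -0.26), and Gca (-1.50, adjusted p = 0.0117), Cttnbp2, Zbtb41, Smarca1 and Shc4 were past the threshold.

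In round spermatid fractions pachytene spermatocyte markers rose with age. Among these markers Aurka rose 1.85-fold, Pttg1 1.83-fold, Cdk1 1.80-fold and Mybl1, a regulator of meiotic genes, 1.70-fold. Cdca8 (1371928_at), of the chromosomal passenger complex, is not on the marker list and was named as 1 of the 10 largest rises. It rose 2.09-fold (log2 change 1.06, SE 0.14, n = 6, limma adjusted p = 0.00177). Of 16 pachytene markers 11 rose and 0 fell (13 and 0 adjusted over the list alone), and the median lay 0.35 above that of all genes (camera, adjusted p = 5.76e-05; 0.642 with an estimated correlation). The list's mean relative to all genes was 2.20 ± 0.17 in young and 2.60 ± 0.10 in aged rats, all 6 aged arrays above every young one. Young rat 10 stood apart on the first principal component of round spermatids (62.2% of the variance; -40.7, against -18.7 to 4.70 in the other young rats), with the lowest pachytene marker level (1.93) and the highest Sertoli (0.0590) and late marker levels. Without that rat the pachytene marker median was 0.30 (adjusted p = 8.80e-06) and that of Sertoli markers -0.17 (8.80e-06). Of 48 genes of cell cycle and meiotic division 20 rose and 6 fell (22 and 14; not past the threshold, 0.109), with Prc1 (0.69), Aurkc (0.46) and Bub1b (0.43) among the former. Of the 16 pachytene markers 7 are on that list too, Aurka, Pttg1 and Cdk1 included, so the counts of these lists overlap. With the pachytene markers' level as a covariate, only 2 probe sets were past the threshold, and none of the 48 genes named for round spermatids kept a call. All 5 list calls in round spermatids were lost in that fit, those of Sertoli markers (adjusted p = 0.0632) and X genes (0.604) included, and its covariate separates the ages completely. Carry-over of spermatocytes was not tested in these fractions, so a rise within spermatids cannot be told apart from it.

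The facilitated glucose transporter gene Slc2a3 (1372326_at) rose most, from 11.6 ± 0.51 to 12.8 ± 0.22 (2.33-fold, SE of the log2 change 0.20, adjusted p = 0.00239). C1h9orf40 rose 2.16-fold, Fyco1, which links autophagosomes to microtubules, 2.11-fold, and Rpa1, of the single-strand DNA-binding complex, 2.10-fold. Trim11, Fam221a, Orc5 and Psip1 rose by 0.92 to 0.90. Of 100 cilium and flagellum genes 26 rose and 10 fell (34 and 14 adjusted over the list alone; median 0.06; camera, adjusted p = 0.0297; 0.72 with an estimated correlation), among them Cfap97 (0.88), Bbs1 (0.64) and Ift46 (0.56) and, falling, Cfap276 (-0.18). The cilium call was lost with median centring (adjusted p = 0.20), cyclic loess (0.0783), the deposited scale (0.927) and a somatic covariate (0.052). Of 36 proteasome genes 11 rose and 0 fell (17 and 4; 0.0531), including Psmd6 (0.66), Psmd8 (0.46), Psmb4 (0.23) and Psmc1 (0.22). Of 51 chaperones 17 rose and 6 fell (22 and 10; 0.0531), and of 51 antioxidant genes 3 rose and 10 fell (4 and 10; 0.549), as Msrb2 (0.29), Srxn1 (-0.63), Gsta4 (-0.27) and Sod1 (-0.23). With median centring Psmb4 (0.110), Psmc1 (0.0585) and Odf4 (0.0955) lost their calls.

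Sertoli cell transcripts fell in aged round spermatid fractions too. Clu (1367784_a_at), which encodes clusterin, fell from 10.9 ± 0.54 to 9.56 ± 0.37 (2.56-fold, adjusted p = 0.00268), Aard 2.13-fold, Cldn11, of Sertoli cell tight junctions, 2.09-fold, and the protease gene Ctsl 2.07-fold. Of 25 Sertoli markers 14 fell and 0 rose, over all probe sets and adjusted over the list alone (median -0.19; camera, adjusted p = 1.45e-05; 0.642 with an estimated correlation), including Cst12 (-0.93) and Amhr2 (-0.42). Outside the Sertoli list, Prnd, Defb24, Serpina5 and Aqp8 were among the 10 largest falls, by 1.17, 1.12, 1.06 and 1.01 on the log2 scale. Cxadr fell in this fraction as well (8.59 ± 1.17 to 7.30 ± 0.08, adjusted p = 0.0451), again through young rats 1, 2, 3 and 11 (8.69 to 9.77, against 7.14 to 7.43 in all others). Wasf2 fell by 0.94 (SE 0.28, adjusted p = 0.0339), although young rat 2 lay low at 9.34. Leaving out any 1 rat other than young 10 and 13 ended the call of Cxadr (adjusted p = 0.0695 to 0.0941), and any 1 other than young 2 and 10 and aged 3 that of Wasf2 (0.0521 to 0.0719). With median centring neither Cxadr (0.0660) nor Wasf2 (0.0915) was past the threshold, and with a mean-variance trend Cxadr was not (0.0765).

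Late spermiogenesis markers and X genes shifted little in round spermatids. Of 24 late markers 7 fell and 1 rose (14 and 2 adjusted over the list alone; median -0.08; camera, adjusted p = 0.0144; 0.72 with an estimated correlation), with Tekt5 (-0.51), Ggn (-0.27) and Akap4 (-0.18) lower and Odf4 (0.24) higher. Ggn lost its call on the deposited scale (-0.04, adjusted p = 0.560), as did Dcaf12l1 (0.166) and Gsta4 (0.0998), and with hybridization controls its change was 0.00365. Of 445 X genes 74 fell and 8 rose (76 and 9; median -0.03; adjusted p = 0.00761; 0.642 with an estimated correlation), a share of 16.6% lower against 10.6% to 16.1% on the autosomes. Tsx (-0.60), Pja1 (-0.47), Magec2 (-0.42) and Dcaf12l1 (-0.22) fell. Most X genes were dim here, with 125 of 445 above the median of all genes in young round spermatids, so falls are compressed. Smaller falls were not past the threshold when arrays were centred on hybridization controls, namely Dcaf12l1, Gsta4, Amhr2, Pja1, Akap4, Cfap276 and Sod1 (adjusted p = 0.0615 to 0.662).

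In all, 5320 of 31042 probe sets (17.1%) were past the threshold in round spermatids, 2670 higher and 2650 lower in aged rats. In a joint fit of all 24 arrays with the rat as random block, 1141 were higher and 672 lower. That fit pools the spread of both cell types, whose median SE was 0.075 in pachytene and 0.041 in round spermatids when fitted apart. It gave 15649 calls in pachytene spermatocytes, against 11643 in the separate fit. The correlation within rats was 0.054, so the lower count in round spermatids cannot be credited to the rat alone. In the joint fit 10 of the 48 genes named for round spermatids lost their call. At a fold of at least 2 there were 7 higher and 9 lower. With hybridization controls 8289 were higher and 427 lower, and on the deposited scale 16477 and 695.

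The age changes of both cell types went the same way more often than not. Across 31042 probe sets, which are not independent of each other, their log2 changes had a Pearson correlation of 0.548 and a Spearman correlation of 0.484. Of 3241 probe sets past the threshold in both cell types, 1704 rose in both and 1319 fell in both, against 591 and 408 for independent lists. Both fractions came from the same rats, and other splits of the rats had a median correlation of 0.239, with 6 of 100 splits, the real one included, at 0.548 or above. The other 218 moved oppositely, 168 of them up in pachytene spermatocytes and down in round spermatids. Aurka (1.71- and 1.85-fold) and Cdk1 (1.75- and 1.80-fold) rose in both fractions, and Aard (2.27- and 2.13-fold) and Pja1 (2.61- and 1.39-fold) fell in both. With the markers of the other germ cell type as a covariate the correlation was 0.0801, with both marker covariates 0.229, and without young rats 1, 10 and 11 it was 0.406.

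**Figure D4:**
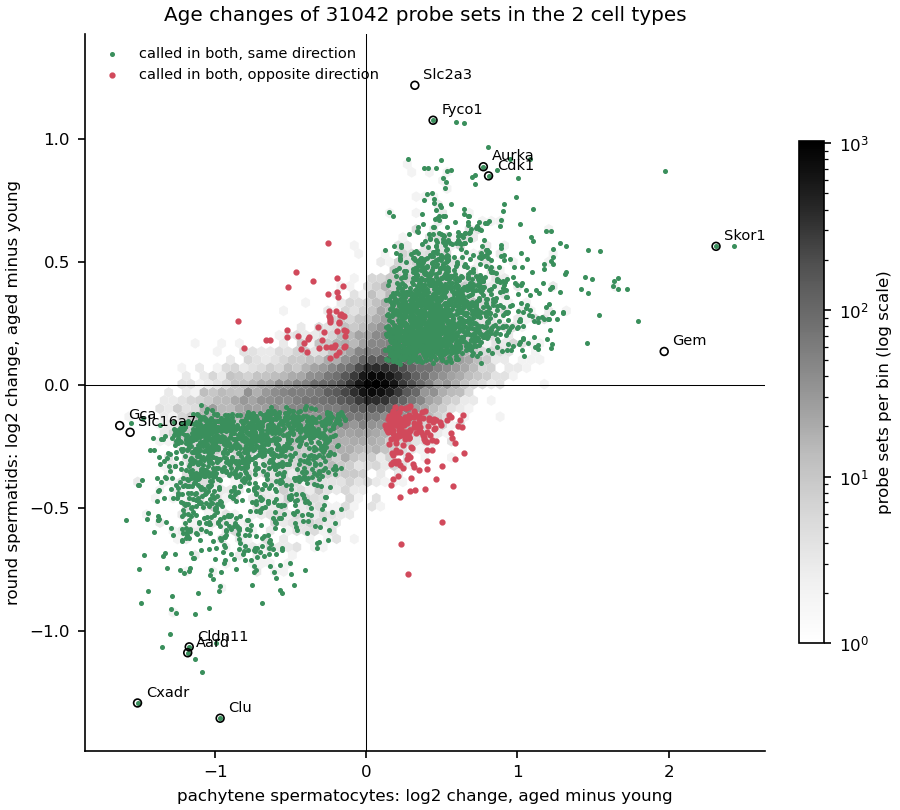
Log2 change with age (aged minus young) of 31042 probe sets in pachytene spermatocytes (x axis) and round spermatids (y axis); grey shows the number of probe sets per bin, green those past the threshold in both with the same sign (3023), red those with opposite signs (218). The Pearson correlation is 0.548 across probe sets and 0.592 on the deposited scale, where nearly all called probe sets are lower in pachytene spermatocytes and higher in round spermatids.

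Whether the age change differed between the cell types was tested directly. The largest positive differences came from falls in pachytene spermatocytes. Slc16a7 went from 12.4 ± 0.95 to 10.7 ± 0.33 in pachytene spermatocytes and from 13.5 ± 0.12 to 13.3 ± 0.13 in round spermatids (difference of the log2 changes 1.51, SE 0.40, n = 6 per group, adjusted p = 0.0151). The X-linked Morf4l2 went from 10.9 ± 0.51 to 9.67 ± 0.18 and from 10.8 ± 0.09 to 10.9 ± 0.05 (1.32, SE 0.21, adjusted p = 0.000672). Vim (1.32, adjusted p = 0.00174), an intermediate filament gene, Lratd1 (1.32, 0.00100) and Spam1 (1.32, 0.0154), a sperm hyaluronidase, differed in the same direction. In the other direction were Asap3 (-1.07, 0.0288), Zfhx3 (-0.98, 0.0115), Sptbn4 (-0.96, 0.0418), Krtcap3 (-0.94, 0.0322) and Glis2 (-0.92, 0.00477), whose change was more positive in pachytene spermatocytes.

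X genes had the most genes with a difference, being the longest list; late spermiogenesis and Sertoli markers had larger shares and medians. Of 445 X genes, 98 were past the threshold in the positive direction and 3 in the negative (131 and 4 adjusted over the list alone; median 0.14; camera, adjusted p = 1.82e-13; 0.413 with an estimated correlation), as Armcx2 (0.61), Smarca1 (0.58) and Rps6ka3 (0.51). In round spermatids Smarca1 lay at 6.73 ± 0.04 and 6.65 ± 0.04, near the background, where a fall could not be measured. Sertoli markers had 7 positive and 0 negative differences of 25 (8 and 0; median 0.21; adjusted p = 0.00054; 0.698 with an estimated correlation), including Inha (0.86), Inhbb (0.71) and Tjp1 (0.53); without young rat 1 the median was 0.12. Late spermiogenesis markers had 10 positive and 1 negative of 24 (15 and 1; median 0.68; adjusted p = 7.40e-05; 0.636), with Hils1 (0.78), Smcp (0.71) and Odf1 (0.68) positive and Ggn (-0.55) negative. In round spermatids Odf1 lay at 15.0 ± 0.02 in both ages, near the top of the range, so changes of these transcripts there are compressed.

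A further 3 lists had a difference. Glycolysis genes had 7 positive and 0 negative differences of 25 (7 and 0; median 0.10; adjusted p = 0.0278; 0.413), with Gapdhs (0.97), Ldhb (0.80) and Pgam1 (0.68), chaperones 8 and 4 of 51 (10 and 4; median 0.16; 0.0158; 0.413), with Hsp90ab1 (0.46), Hspa4 (0.39), Cct5 (0.15) and Dnajb2 (-0.35), and mitochondrial ribosomal proteins 0 and 18 of 73 (0 and 22; median -0.11; 0.000406; 0.698), with Mrps25 (-0.43), Mrpl48 (-0.39), Mrpl52 (-0.35) and Mrpl50 (-0.27). The third value in each bracket is camera's adjusted p and the last that with an estimated correlation. Glycolysis lost its call without young rat 1 (adjusted p = 0.051) or aged rat 3 (0.0517). With median centring, the late spermiogenesis, chaperone, glycolysis and mitochondrial ribosomal calls were lost (0.443 to 0.447), Cct5 had a difference of -0.21, and Odf1, Hils1, Smcp, Mrpl50 and Gapdhs lost their calls (0.0566 to 0.236). On the deposited scale after the background offset the camera direction of the late spermiogenesis (0.122), chaperone (0.215) and glycolysis (0.698) lists turned negative, and the Sertoli list lost its call (0.394). On that scale Mrpl48 (0.10) and Mrpl50 (0.16) had positive differences, and Ggn, Mrps25, Mrpl52, Dnajb2, Cct5, Asap3, Sptbn4 and Krtcap3 were not past the threshold (0.0516 to 0.961).

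In all, 4057 of 31042 probe sets (13.1%) had an age change that differed between the cell types, 1855 in the positive direction (round spermatids minus pachytene spermatocytes) and 2202 in the negative. Of the 86 with a difference of at least 2-fold, 84 were positive. Without aged rat 5 the count was 2444, and without aged rat 8 it was 2317. The split was 2851 and 8333 with median centring and 25091 and 27 on the deposited scale after the background offset. Asap3, Sptbn4, Krtcap3 and Dnajb2 lost their calls with array weights (adjusted p = 0.0566 to 0.135). Asap3, Sptbn4 and Krtcap3 also lost them without any 1 of young rats 1, 10 and 11 or aged rats 3, 5, 8 and 9 (0.0512 to 0.0973), Sptbn4 and Krtcap3 without aged rat 10, and Sptbn4 without aged rat 2. Without young rats 1, 10 and 11, Spam1, Asap3, Zfhx3, Krtcap3, Hils1, Smcp, Gapdhs, Cct5 and Dnajb2 were not past the threshold (0.0582 to 0.122). Gapdhs lost its call without aged rat 5 (0.0510), and Pgam1 without aged rat 5 (0.0642) or 8 (0.0538).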

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

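Single arrays stood apart from their group in 7 of 208 groups of named genes and in 0 of 20 groups of lists, where about 1 in 20 would by chance. The flags are thus no more than chance would give, and none alone sets a rat apart. The gap of the extreme array over the range of the group had to exceed 0.625. Young rat 1 was highest in pachytene spermatocytes for Smarca1 (gap 0.665; 7.93 against a mean of 7.33 in the others) and Inha (0.652; 10.6), which widens the falls of both genes. Aged rat 2 was highest for Odf1 (0.635; 14.1 against 13.7) and Smcp (0.729; 13.8 against 13.3) and lowest for Bard1 (0.629; 8.28 against 8.49). Odf1 and Smcp are both late spermiogenesis markers. That list's level in aged rat 2 (4.22 relative to all genes) was not flagged but lay within the range of the young rats (4.10 to 5.06). Aged rat 8 was lowest for Bag2 (0.634; 8.22 against 8.54). Young rat 2 was lowest in round spermatids for Wasf2 (0.686; 9.34).

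Results that differed between the cell types were those past the threshold for the difference of the age change. Among lists these were late spermiogenesis markers (0.68), Sertoli cell markers (0.21), chaperones (0.16), X chromosome genes (0.14), glycolysis (0.10) and mitochondrial ribosomal proteins (-0.11). Among genes they were Slc16a7 (1.51), Vim (1.32), Lratd1 (1.32), Morf4l2 (1.32), Spam1 (1.32), Asap3 (-1.07), Zfhx3 (-0.98), Sptbn4 (-0.96), Krtcap3 (-0.94) and Glis2 (-0.92). Most stem from a change in pachytene spermatocytes that was small in round spermatids. For Hils1, Smcp and Odf1 the signal in round spermatids was near the top of the range, and for Smarca1 near the background, so a difference there can come from the scale.

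For spermatid transcripts, both tests were written before their values were seen. Probe sets outside the marker lists that were at least 4-fold higher in round spermatids had a median change of -0.98 in aged pachytene fractions (-1.15 to -0.76 without 1 rat, 440 probe sets, 321 lower and 0 higher). That value is consistent with carry-over of spermatids or their cytoplasm, in larger amounts in young fractions, although the set was selected on the same arrays. Without the quantile step the late list's median was -0.54, a value that shifts of whole arrays cannot move, and with cyclic loess -0.88, but its call was lost on the deposited scale and with hybridization controls, so the part of scaling stays open. A change in spermatid transcripts within spermatocytes was not tested and stays open.

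For Sertoli cell markers, the test of all somatic cells alike was chosen only after the result was seen. The smallest difference between another somatic list's mean change and that of the Sertoli list was 0.57 (0.50 to 0.63 without 1 rat), but the other lists are dim (5 of 19 Leydig, 4 of 13 peritubular, 6 of 34 macrophage and 2 of 15 endothelial markers above the median of all genes in young pachytene fractions), so a lower share of all somatic cells stays open. Called Sertoli markers rose and fell together between arrays, with a median correlation to the mean of the others of 0.906 (quartiles 0.837 to 0.942). It was 0.963 within young and 0.862 within aged rats. Carry-over of Sertoli cells or their fragments would give such a value, but other called genes were not compared. The first principal component held 73.9% of the variance of these arrays, so other called genes may move together as well. The value therefore cannot decide on carry-over of Sertoli cells. Scaling was argued against, as the median was -0.88 without the quantile step, where shifts of whole arrays cannot move it, and -1.07 with cyclic loess. Of the 25 markers 4 lie on the X chromosome, and 17 were above the median of all genes in young pachytene fractions.

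For X chromosome genes, the covariate fit was an added alternative. With late spermiogenesis and somatic markers as covariates, the median was -0.14 (-0.17 to -0.12 without 1 rat). That lies between the full fall and none, so carry-over of other cells stays open. The covariates move with age and take away power. The somatic covariate averaged the Sertoli, Leydig, peritubular, macrophage and endothelial lists alike. Their mean log2 age changes were -0.74 for Sertoli markers and -0.17 to 0.08 for the others, so it may follow Sertoli cells only in part. Spermatids alone were argued against, as the 159 X genes lower in round spermatids had a median of -0.84 (-0.90 to -0.70). Scaling was argued against, as the median was -0.51 without the quantile step, where shifts of whole arrays cannot move it, and -0.44 with cyclic loess. Sertoli cells, which express X genes, remain a possible source, and a change of X expression in spermatocytes with age was not tested apart from them.

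Splits of the rats bear on the counts. The real split gave 11643 calls in pachytene spermatocytes, 5320 in round spermatids and 4057 for the difference, and in each case 1 of 100 splits, the real one, was as high, with 1 call in the highest other. For the cell types, in a fit of both groups, the real 25831 was matched by 1 of 100 (highest other 24112). For the correlation of the age effects (0.548), 6 of 100 splits were as high (highest other 0.576), so chance is not excluded for that value.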

How the results depend on the processing

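In pachytene spermatocytes 11643 calls became 3262 with a fold of 1.5, 3364 with unadjusted p and that fold, 6600 with 1 probe set per gene, 19153 on the deposited scale, 7651 without young rats 1, 10 and 11, 2566 with markers of the other germ cell type as covariate, 4425 with somatic markers, 3617 with both and 1101 with late spermiogenesis and somatic markers (8949 to 12542 without 1 rat). Fanca changed sign on the deposited scale (-0.0208), and Gem (-0.0583), Ddit4l (-0.0723) and Cacna1h (-0.264) with late spermiogenesis and somatic covariates. In round spermatids 5320 calls became 332 with the fold, 337 with unadjusted p, 3546 with median centring, 17172 on the deposited scale, 8716 with hybridization controls, 2 with the other germ cell's markers, 3 with both covariates and 1813 in the joint fit of both cell types with the rat as random block (3614 to 6551 without 1 rat). Ggn changed sign with hybridization controls (0.00365). With the other germ cell's markers Trim11 (-0.0700), Psip1 (-0.0307), Aurka (-0.0642), Tekt5 (0.0301), Srxn1 (0.00192), Sod1 (0.000197) and the pachytene (-0.0473), cilium (-0.0227) and late spermiogenesis (-0.00296) lists did, the pachytene list by construction, as its own level was the covariate, and the Sertoli and X list calls were lost. With both covariates all list calls but that of Sertoli markers were lost. The pachytene marker level separates the ages in round spermatids completely, so lost calls need not mean absent effects. With a replicate block over numbers shared by different rats, the counts were 363 and 0; such a block leaves few rats, and a call lost under it is not a weaker effect. Between cell types 26420 became 8734 with the fold under either p, 16869 without the dimmest probe sets and 12525 with 1 probe set per gene (26052 to 26289 without 1 rat). For the difference 4057 became 579 with the fold, 827 with unadjusted p, 11184 with median centring, 25118 on the deposited scale after the offset, 2511 with 1 probe set per gene and 2615 without young rats 1, 10 and 11 (2317 to 4830 without 1 rat; aged rat 5, 2444; aged rat 8, 2317). Cct5 changed sign with median centring (-0.21), Mrpl48 (0.10) and Mrpl50 (0.16) on the deposited scale after the offset, and there camera's direction did for the late spermiogenesis (0.34), chaperone (0.0736) and glycolysis (0.0887) lists. List calls (26 in all) were 0 with an estimated correlation in each comparison; fry gave 14 in pachytene spermatocytes, 8 in round spermatids, 31 between cell types and 2 for the difference, 55 in all. The correlation of age effects (0.548) was 0.0801 with the other germ cell's markers, 0.366 with somatic markers, 0.229 with both and 0.406 without young rats 1, 10 and 11 (0.517 to 0.559 without 1 rat). With 1 probe set per gene 14217 probe sets were tested, and 18625 without the dimmest, instead of 31042. The lower counts under these settings are therefore out of fewer probe sets. The cause of the other shifts was not tested. Values are log2 already, so no pseudocount was tried.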

Other observations

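A few transcripts marked single rats in both fractions. Rgs7bp (1383726_at), a regulator of G protein signalling, was at 6.98 in pachytene spermatocytes of young rat 10 and at 4.13 to 4.46 in the other 11 rats, and at 9.17 against 6.72 to 7.02 in round spermatids. Plekha6 (1379536_at) was highest in the same rat (7.97 against 6.35 to 6.87, and 9.24 against 7.46 to 7.65). C1s (1387893_at), a complement protease gene, was highest in aged rat 5 (7.84 against 5.96 to 6.94, and 10.3 against 8.25 to 8.86). These 3 were found by a screen chosen after the values were seen: of 20 probe sets with a within-age SD of at least 0.4 in both fractions, 3 correlated at 0.9 or more over rats, and shuffling rats within age gave a median of 0 and at most 3 in 100 shuffles.

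The level of X genes varied with other lists within an age in pachytene spermatocytes. These relations were not in the plan. Relations among other lists were not computed, so a link particular to X genes cannot be read from them. Of 6 relations (n = 6 rats each, exact permutation), X genes fell as pachytene markers rose among young rats (Pearson -0.99, p = 0.00139, adjusted 0.00417; Spearman -1, p = 0.00278, adjusted 0.00833; Pearson -0.997 without the 2 farthest rats). Among young rats they rose with late spermiogenesis markers (Pearson 0.941, p = 0.00556, adjusted 0.0111; Spearman 0.943, p = 0.0167, adjusted 0.0333; 0.907 without the 2 farthest). Their relation to Sertoli markers among young rats (Pearson 0.911, p = 0.0222, adjusted 0.0333; Spearman 0.60, p = 0.242, adjusted 0.363) rested on 2 rats (-0.147 without them). Among aged rats X genes rose with Sertoli markers (Pearson 0.967, p = 0.00139, adjusted 0.00417; Spearman 1, p = 0.00278, adjusted 0.00833; 0.899 without the 2 farthest). Late markers (Pearson 0.659, p = 0.151, adjusted 0.174; Spearman 0.257, p = 0.658, adjusted 0.658; -0.972 without the 2 farthest) and pachytene markers (-0.645, p = 0.174, adjusted 0.174; -0.314, p = 0.564, adjusted 0.658; -0.429) were not past the threshold there.

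With late spermiogenesis and somatic markers as covariates the X median was -0.14, in a fit whose late spermiogenesis covariate nearly separates the ages. Staining the fractions for SOX9, a nuclear protein, could test whether whole Sertoli cells carry the X signal, but would miss fragments. Smarca1 and Pja1 could also be measured in spermatocytes sorted by DNA content from 4 and 18 month old rats. If X expression itself fell in aged spermatocytes, the fall would remain in sorted cells.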
